A study of Mus musculus with 16 samples.

How the data were processed

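RNA of 16 libraries was analysed, 4 each of wild-type pro-B, Il33-/- pro-B, wild-type large pre-B and Il33-/- large pre-B cells from BALB/c bone marrow. Per the labels, CD19-positive cells were enriched magnetically and then sorted by flow cytometry, RNA was taken with RNeasy columns, and stranded poly-A libraries were made. The deposited file holds raw read counts, whole numbers per Ensembl gene, for 27494 genes with their symbols and biotypes and no other per-sample values (0 further columns). The submitters' notes name mm10, MultiQC 1.2 and edgeR without a version. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. The columns were assigned to groups by the sample titles, and replicate numbers follow the order of deposit, so no libraries were paired. Positions come from GENCODE vM21 on mm10 and were found for 27306 genes, while 188 had none.

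Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 15377. Counts were scaled by TMM factors and fitted by the edgeR quasi-likelihood method (edgeR 4.0.16 in R 4.3.3, robust) with 1 mean per group over all 16 libraries, which gives 12 residual degrees of freedom. Contrasts of that fit tested genotype in pro-B cells, genotype in large pre-B cells, the difference between these effects, their mean, and stage in wild type and in Il33-/- cells. P-values were two-sided and adjusted by Benjamini-Hochberg over the tested genes of each contrast, with a threshold of 0.05 (edgeR adjusted p). The standard error of a log2 fold change was taken as its size over the root of the F statistic. Il33, Il1rl1 and Il1rap were also tested by an exact permutation of their CPM.

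A set of 37 gene lists, 32 written by gene name (846 genes, of which 3 are not in the file) and 5 by symbol pattern, was tested with camera (limma 3.58.1) at its preset correlation of 0.01, and adjusted over the lists of a contrast, each with at least 3 tested members. Camera with an estimated correlation and fry stood beside it, and for each list the members were also adjusted over the list alone. The lists covered DNA replication, E2F-regulated cell cycle genes, G2/M and mitosis, p53 target genes, CDK inhibitors and the RB family, the BCL2 family, early B cell identity, the pre-B cell receptor and its signalling, V(D)J recombination, IL-7 receptor signalling, late pre-B to mature B cell genes, interferon-stimulated genes, NF-kB target genes, MYC targets and ribosome biogenesis, glycolysis and hypoxia, oxidative phosphorylation, cholesterol biosynthesis, the unfolded protein response, immediate early and heat shock genes, the IL-1 and IL-33 family, chromatin partners, and markers of other cells. The patterns were histones, heavy chain V segments, light chain V segments, mitochondrially encoded genes and ribosomal proteins.

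Correlations of the genotype effects of both stages ran across genes. Genes within 10 Mb of Il33 were compared with all others by Fisher's exact test. Other splits of the libraries were counted, all 35 for 4 against 4, and 100 including the real one, drawn with a fixed seed, for the difference, the mean and the correlation.

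Named genes followed a rule set before the data were examined, as were the contrasts, tests, lists and most alternatives. Il33, Il1rl1 and Il1rap are always named. For each genotype comparison and for stage in wild type, the 10 largest rises and 10 largest falls are named among protein-coding genes past the threshold whose 4 libraries all lie on one side of the other 4, with a mean of at least 1 CPM over the 8. Up to 4 members of lowest p are named from each list described, and the 10 genes of lowest p for the difference between stages. Immunoglobulin and T cell receptor segments (420 in the file) and predicted genes were counted but not among the 10.

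The alternatives were DESeq2 size factors, upper quartile factors and no scaling factors; no filter, or at least 1 CPM in 4 libraries; the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, and limma-voom with quality weights; the compared groups alone; protein-coding genes only; no genes of chromosomes X and Y; an adjusted p under 0.01; at least 1.5-fold; lists without shared members; windows of 5 and 20 Mb; a Spearman correlation and genes above 10 CPM; and leaving out each library. Leaving out the 95 ribosomal RNA genes, leaving out Il33-/- pro-B replicate 1 where a contrast does not use it, leaving out libraries for the correlation and the window around Il33, and upper quartile factors and the CPM filter for the lists were chosen after seeing the data.

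Library totals ran from 7.96 to 30 M counts. The tests were tried on simulated data, where 200 genes were changed in counts like those of each stage. In pro-B cells (15120 genes) edgeR recovered 68.2%, 89.6% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale with 3.8% false calls, against 10.9% for DESeq2 and 9.2% for limma-voom. In large pre-B cells (15125 genes) it recovered 69.7%, 83.6% and 97% with 3.88% false calls, against 8.37% and 5.6%. The simulated counts were drawn with edgeR's own estimates of spread, so the comparison of tools may favour edgeR. A planted list was recovered in both, with 0 and 1 other lists past the threshold by camera and 9 and 4 by fry. Genes were simulated independently of each other, so this does not measure false list calls under the correlations between real genes. Other splits of the real libraries passed a median of 11 lists in pro-B and 9 in large pre-B cells by camera at the preset correlation. No library was left out of the main tests, and replicates correlated at 0.978 to 0.997 on the log scale.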

Results

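Polyadenylated RNA was sequenced from B cell precursors of BALB/c mouse bone marrow, either wild type or lacking Il33. Il33 encodes interleukin-33, a cytokine of the IL-1 family that is also held in the nucleus. Cells carrying CD19, a surface protein of the B lineage, were enriched on magnetic beads and sorted as pro-B cells, which assemble the immunoglobulin heavy chain gene, or as large pre-B cells, the dividing stage that follows. There were 4 groups of 4 libraries, which were wild-type pro-B, Il33-/- pro-B, wild-type large pre-B and Il33-/- large pre-B. The deposited table held whole read counts for 27494 genes, and 15377 of them had enough reads to be tested. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

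The 4 wild-type pro-B libraries held 23734032, 29930296, 26153698 and 24629353 counts. The 4 wild-type large pre-B libraries held 22464193, 26404768, 28699738 and 25302679. The Il33-/- large pre-B libraries held 27405314, 29995174, 27564682 and 27690896. Among the Il33-/- pro-B libraries, replicates 2 to 4 held 27031053, 25063506 and 25175011, and replicate 1 held 7964898. In that replicate 38.5% of the counts fell on 95 genes of ribosomal RNA or with ribosomal RNA fragments, against 0.278 to 0.321% in the other 3 of its group. This left it 4.90 M counts. Histone genes took 0.164% of its counts against 0.0126 to 0.0179% in the other 3. On the first principal component, which held 67.6% of the variance, all 8 pro-B libraries were parted from all 8 large pre-B libraries. The second, with 9.04%, set Il33-/- pro-B replicate 1 at -82.7 apart from the rest.

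**Figure D1:**
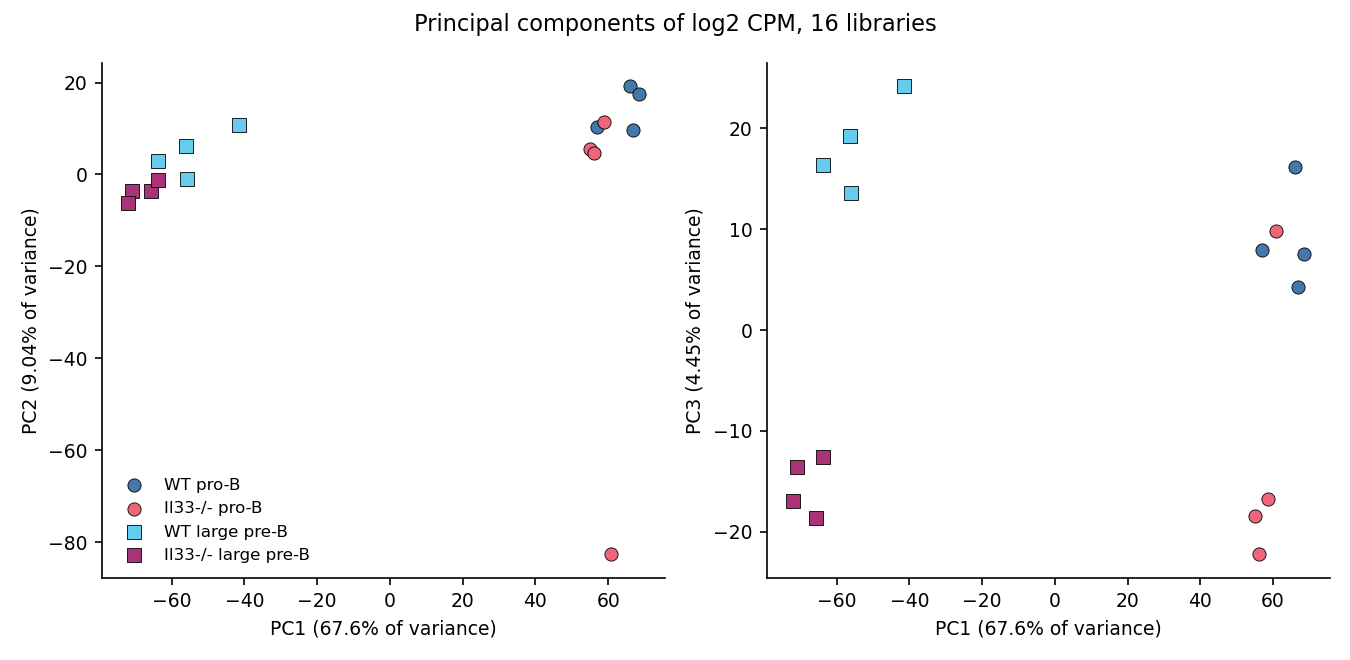
Principal components of the 16 libraries (each point is 1 library), with the share of the variance on each axis. The first component (67.6%) parts the stages, and the second (9.04%) parts Il33-/- pro-B replicate 1, at -82.7, from the other libraries.

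Il33 was transcribed at both stages in wild-type cells and was lower, without being lost, in the Il33-/- cells. Its transcripts stood at 16.8 ± 2.29 CPM (read counts scaled to library size by TMM factors; mean ± SD, n = 4 libraries here and in all group values that follow) in wild-type pro-B and 7.65 ± 1.60 in wild-type large pre-B cells. In Il33-/- pro-B cells they stood at 2.66 ± 0.661 and in Il33-/- large pre-B cells at 0.867 ± 0.177, which was 15.8% and 11.3% of the wild-type level. The log2 fold change was -2.61 (SE 0.18, edgeR adjusted p = 1.5e-09) in pro-B and -3.13 (SE 0.20, adjusted p = 4.0e-10) in large pre-B cells. The 4 libraries of each group did not overlap (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 can give). The gene (ENSMUSG00000024810) lies on chromosome 19 from 29925114 to 29960718 in mm10. The labels do not say which part was deleted, and reads from outside that part check nothing. Il33 also fell from pro-B to large pre-B in wild type by 1.13 on the log2 scale (SE 0.16, adjusted p = 1.2e-06) and in Il33-/- cells by 1.66 (SE 0.22, adjusted p = 4.7e-07).

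Transcripts of the IL-33 receptor were scarce in these cells. Il1rl1, which encodes the receptor chain ST2, stood at 0.457 CPM in wild-type and 0.587 CPM in Il33-/- pro-B cells, and at 0.123 and 0.12 CPM in large pre-B cells. Il1rap, which encodes the chain shared with other IL-1 family receptors, stood at 13.4 and 13.3 CPM in pro-B and at 9.38 and 8.98 CPM in large pre-B cells. Neither differed between genotypes past the threshold, with adjusted p = 0.955 and 0.996 for Il1rl1 and 0.962 and 0.847 for Il1rap in pro-B and large pre-B cells. Both fell with stage in wild type, Il1rl1 by 1.86 (SE 0.59, adjusted p = 0.0092) and Il1rap by 0.51 (adjusted p = 0.00033) on the log2 scale. For Il1rl1 the libraries of both stages overlapped at these low levels, and an exact permutation did not pass (p = 0.0571).

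**Figure D2:**
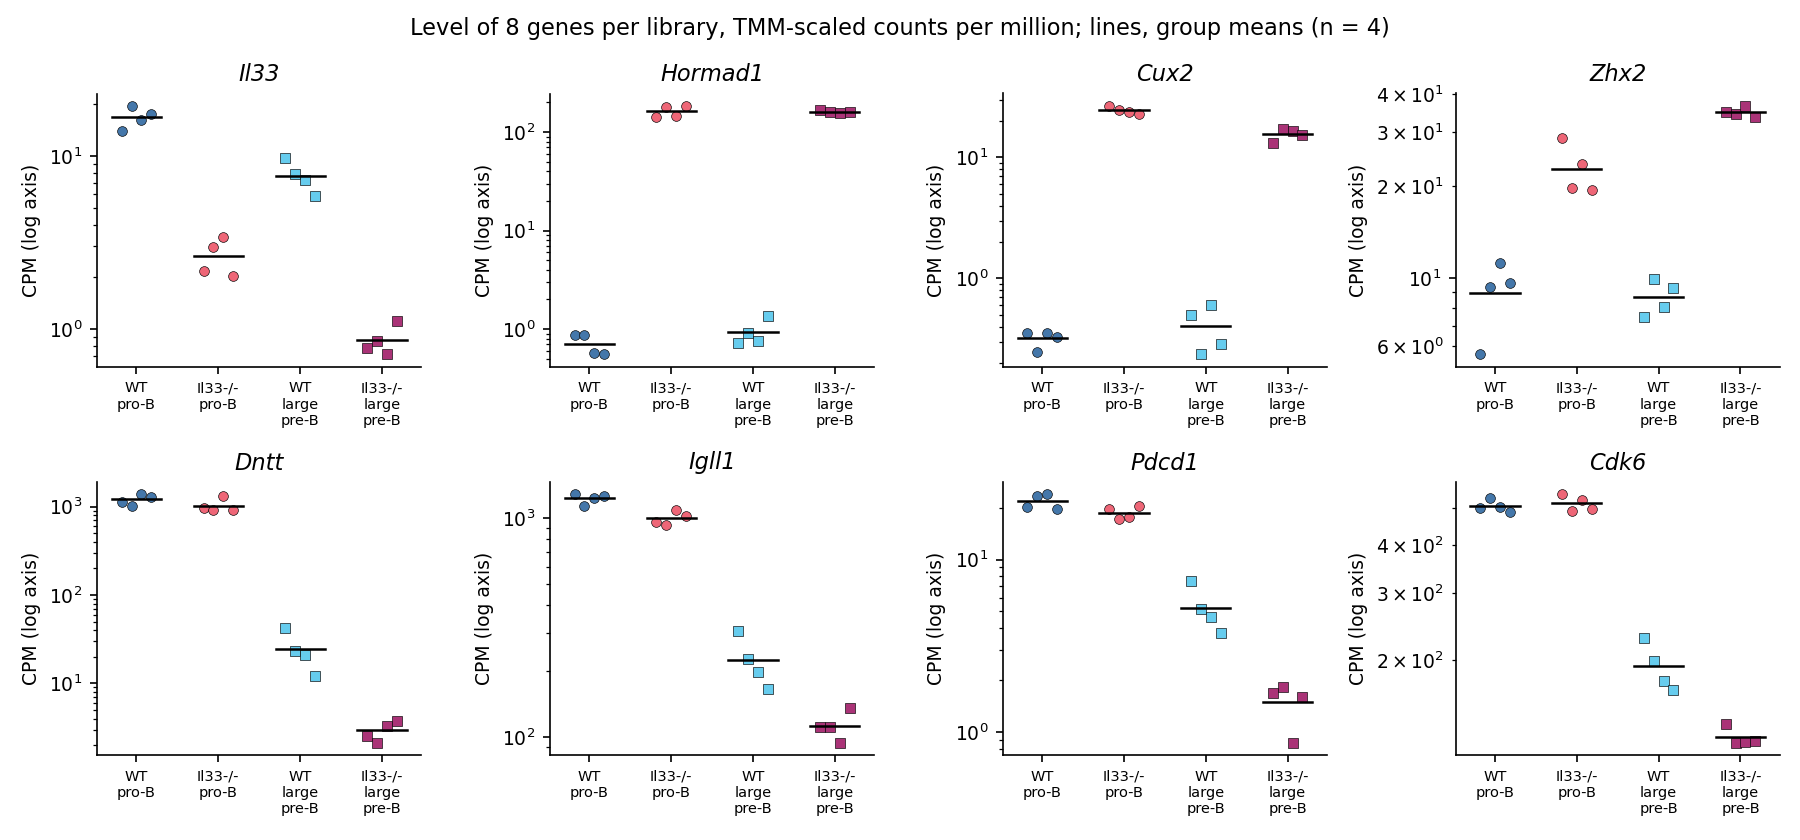
CPM of 8 genes on log axes in each of the 16 libraries (points), by group, with the group means as lines. Il33 is lower and Hormad1, Cux2 and Zhx2 are higher in Il33-/- libraries of both stages, whereas Dntt, Pdcd1 and Cdk6 part by genotype in large pre-B cells and overlap in pro-B cells, and Igll1 parts at both stages without passing in pro-B cells; Dntt, Igll1, Pdcd1 and Cdk6 were chosen after their values were seen.

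The first comparison asks which transcripts differ between wild-type and Il33-deficient pro-B cells. The meiotic gene Hormad1 rose from 0.710 ± 0.174 to 163 ± 22.1 CPM, the homeobox gene Cux2 from 0.321 ± 0.0509 to 24.5 ± 1.63 CPM, and the transcription factor gene Zhx2 from 8.97 ± 2.38 to 22.8 ± 4.34 CPM. Transcripts of immunoglobulin genes rose as well. Igkc, the constant part of the kappa light chain, went from 319 ± 57.7 to 600 ± 28.9 CPM (log2 fold change 0.91, SE 0.09, adjusted p = 2.2e-05). Tfe3, which encodes a transcription factor of lysosome and metabolic genes, fell from 58.7 ± 2.09 to 32.2 ± 3.17 CPM. Gimap4, which encodes a GTPase of lymphocytes, fell from 26.2 ± 4.44 to 8.33 ± 1.03 CPM. In total 207 genes passed an adjusted p of 0.05, 110 higher and 97 lower in Il33-/- cells. Of these, 154 were protein-coding, 28 were immunoglobulin or T cell receptor segments and 66 changed more than 2-fold.

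Hormad1 (ENSMUSG00000028109, chromosome 3, 95559677 to 95587671) had a log2 fold change of 7.83 (SE 0.14, adjusted p = 2.2e-18) in pro-B cells. Cux2 (ENSMUSG00000042589, chromosome 5, 121856366 to 122050102) rose by 6.24 (SE 0.18, adjusted p = 2.3e-17), and Zhx2 (ENSMUSG00000071757, chromosome 15, 57694665 to 57839832) by 1.30 (SE 0.16, adjusted p = 1.4e-04). Both overlap antisense genes that were counted too (Gm15637 at Cux2, 9330154K18Rik and Gm16006 at Zhx2, chosen after their values were seen), and the strand used in counting is not stated. The kinase gene Pak1 rose by 2.22 and Adarb2, which encodes a relative of the RNA-editing enzymes, by 1.72. Erdr1 (2.13) and Mid1 (1.27) lie at the pseudoautosomal boundary in repeated sequence, and Ly6c2 (1.38) belongs to a multigene family, so reads of these 3 genes are uncertain. The call for Ly6c2 was lost without wild-type pro-B replicate 1, 2 or 3 or Il33-/- pro-B replicate 4. Of the remaining large rises, Cryab (1.42) lost its call without wild-type pro-B replicate 3, and Ccr10 (1.76) lost it without any 1 of the wild-type pro-B libraries or Il33-/- pro-B replicate 3.

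Among the falls in pro-B cells, Gimap4 (ENSMUSG00000054435, chromosome 6, 48684549 to 48692060) had a log2 fold change of -1.63 (SE 0.14, adjusted p = 8.6e-08) and Tfe3 (ENSMUSG00000000134, chromosome X, 7762560 to 7775202) of -0.89 (SE 0.06, adjusted p = 1.8e-09). The DNA repair homologue gene Alkbh7 fell from 10.2 ± 0.599 to 4.05 ± 0.679 CPM (-1.29, SE 0.14, adjusted p = 3.1e-06). Slc9a9 fell by 1.40, the chemokine gene Ccl25 by 1.07 and the oxygen sensor gene Egln3 by 0.92 on the log2 scale. Speer2, of a multigene family and so uncertain, fell by 1.5 and lost its call without wild-type pro-B replicate 3. The call for Rgs8 (-1.06) was lost without wild-type pro-B replicate 3 or 4 or Il33-/- pro-B replicate 2 or 3. Rcan2 (-0.96) lost its call without wild-type pro-B replicate 1, 3 or 4 or Il33-/- pro-B replicate 2 or 4.

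The immunoglobulin transcripts were higher in Il33-/- pro-B cells across most segments. Of 108 heavy chain V segments 93 had a positive log2 fold change (median 0.47). Of them 15 rose and 0 fell, or 37 and 0 adjusted over the list alone (camera adjusted p = 7.4e-20; adjusted p = 1.1e-04 with an estimated correlation). The summed heavy chain V segments went from 293 ± 18 to 428 ± 19 CPM. Of 87 light chain V segments 71 were higher (median 0.72). Of them 7 rose and 0 fell, or 26 and 2 adjusted over the list alone (adjusted p = 2.3e-11; adjusted p = 0.0050 with an estimated correlation). Ighv3-6, Ighv6-3, Ighv9-3 and Ighv1-21 rose by 1.36, 1.42, 0.76 and 1.54 on the log2 scale. V segments and the constant regions of the heavy chains share sequence, so reads of a single segment or isotype are uncertain.

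Plasma cell genes were higher with them. Of 14 plasma cell markers 13 were higher (median 0.46). Of them 3 rose and 0 fell, or 6 and 0 adjusted over the list alone (adjusted p = 7.1e-06; adjusted p = 0.0040 with an estimated correlation). Jchain (ENSMUSG00000067149), which joins secreted IgA and IgM, rose from 94.5 ± 24.5 to 221 ± 18.8 CPM (1.23, SE 0.23, adjusted p = 0.019) and lost its call without wild-type pro-B replicate 1. Igha, the constant region of IgA, went from 258 ± 55.9 to 802 ± 104 CPM (1.64, SE 0.31, adjusted p = 0.023), a call lost without wild-type pro-B replicate 1, 2 or 3. Ighg3 rose by 1.24 (adjusted p = 0.028), a call lost without wild-type pro-B replicate 3 or Il33-/- pro-B replicate 2, 3 or 4. Sdc1, which encodes CD138, was 0.33 higher without passing (adjusted p = 0.062). The late pre-B, immature and mature B cell list was higher too, with 5 of 32 genes that rose and 0 that fell, or 9 and 2 adjusted over the list alone (adjusted p = 1.2e-05; adjusted p = 0.227 with an estimated correlation). Beside Igkc it held Iglc1 (1.46, adjusted p = 0.017, lost without wild-type pro-B replicate 1 or 3). Cd38 rose by 0.52 (adjusted p = 0.026), a call lost without wild-type pro-B replicate 2 or Il33-/- pro-B replicate 1, 2 or 3. Cd36 rose by 0.99 (adjusted p = 0.035), a call kept only without wild-type pro-B replicate 4 or Il33-/- pro-B replicate 1. Ms4a1, which encodes CD20, stood at 9.48 CPM in wild-type and 8.59 CPM in Il33-/- pro-B cells, and was chosen after its values were seen.

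**Figure D3:**
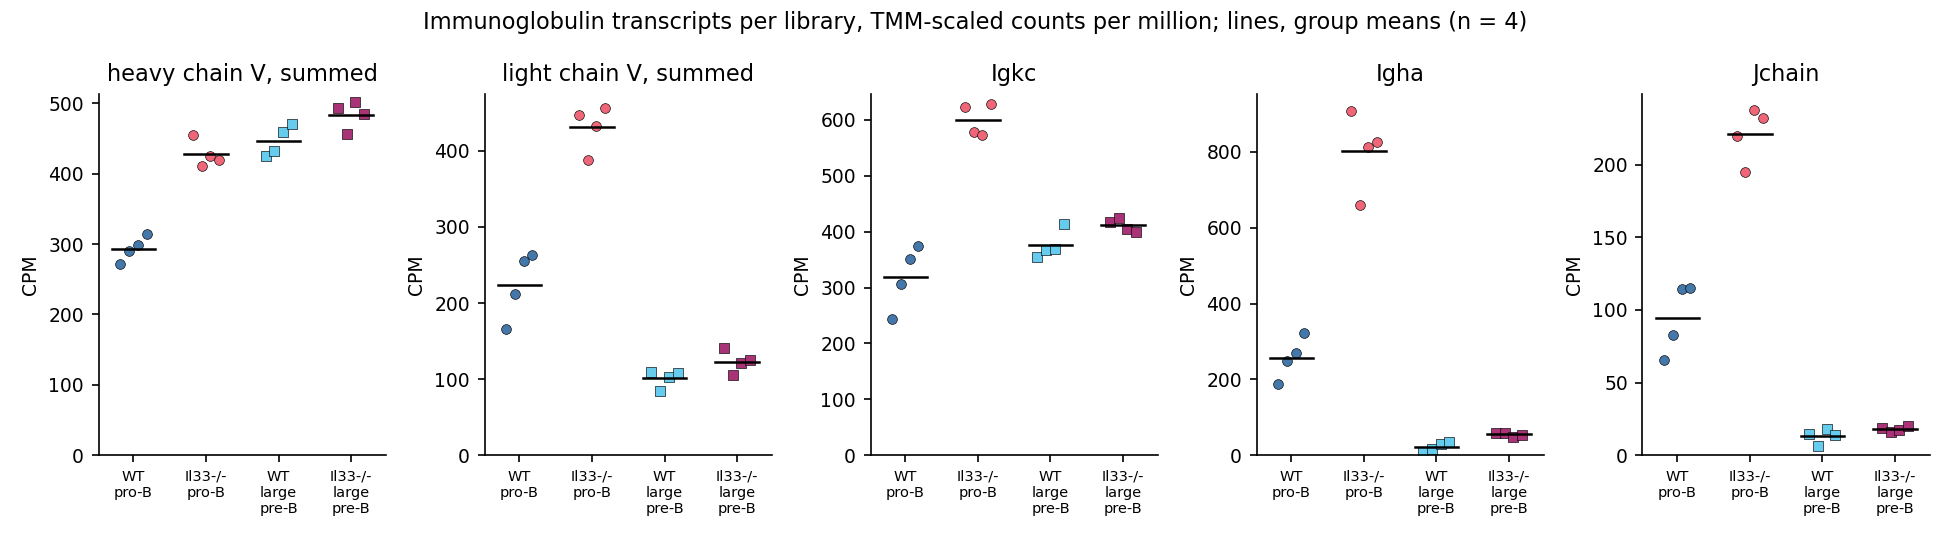
CPM of the summed heavy chain V segments, the summed light chain V segments, Igkc, Igha and Jchain in each of the 16 libraries (points) by group. In pro-B cells the heavy chain V sum goes from 293 to 428 CPM and Igkc from 319 to 600 CPM between wild type and Il33-/-, and in large pre-B cells Igkc stands at 376 and 411 CPM and Igha at 22.8 and 55.4 CPM.

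Interferon-stimulated genes were slightly higher in Il33-/- pro-B cells. Of 38, 31 were higher (median 0.10). Of them 2 rose and 0 fell, or 7 and 0 adjusted over the list alone (adjusted p = 7.9e-06; adjusted p = 0.404 with an estimated correlation). Ifi27l2a rose from 11.7 ± 2.10 to 23.2 ± 4.56 CPM (1.03, SE 0.15, adjusted p = 0.0022), and Oasl1 by 0.56 (adjusted p = 0.048), a call that was lost without any 1 of the 8 pro-B libraries. Genes of the precursor programme moved little. Ccnd3, which encodes cyclin D3, rose from 855 ± 43.1 to 1070 ± 66 CPM (0.32, SE 0.06, adjusted p = 0.0029). Enpep, which encodes the BP-1 surface marker, rose by 0.46 (SE 0.09, adjusted p = 0.0087). Of the IL-7 receptor list 1 gene rose (1 and 1 fell adjusted over the list alone), of the early B cell identity list 1 (2 and 0) and of the V(D)J recombination list 1 (1 and 0), with adjusted p = 0.374, 0.902 and 0.23 for the lists. The last was Polm, whose call was kept only without wild-type pro-B replicate 2 or Il33-/- pro-B replicate 3. Of the 26 genes of the pre-B cell receptor list 12 were higher, and 2 rose and 1 fell adjusted over the list alone (list adjusted p = 0.937).

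Cell cycle lists were higher in Il33-/- pro-B cells by a small margin. The DNA replication list, with 45 of 49 genes higher, had adjusted p = 2.6e-06 (adjusted p = 0.722 with an estimated correlation), the E2F list, with 34 of 40, 1.2e-05 (0.722) and the G2/M and mitosis list, with 48 of 59, 0.024 (0.899). The glycolysis and hypoxia list was lower, with 1 fall, Egln3, or 3 adjusted over the list alone (adjusted p = 0.0026; adjusted p = 0.722 with an estimated correlation). Cholesterol biosynthesis was lower with 1 fall, Srebf2, which lost its call without wild-type pro-B replicate 1, 3 or 4 or Il33-/- pro-B replicate 2 or 3 (list adjusted p = 0.0103; adjusted p = 0.743 with an estimated correlation). Immediate early and heat shock genes were lower (adjusted p = 0.0080; adjusted p = 0.797 with an estimated correlation). Their 1 fall was Nr4a1 (-0.57, adjusted p = 0.026), lost without wild-type pro-B replicate 3 or 4 or Il33-/- pro-B replicate 2 or 3. The unfolded protein response list was higher with 2 rises, or 6 and 1 fall adjusted over the list alone (adjusted p = 0.0154; adjusted p = 0.722 with an estimated correlation). They were Hsp90b1 (0.24, adjusted p = 0.0044) and Pdia4 (0.21, adjusted p = 0.019), the latter kept only without Il33-/- pro-B replicate 1. The IL-1 and IL-33 family list was lower with 1 fall, Il33 itself (adjusted p = 0.0061; adjusted p = 0.0607 with an estimated correlation). Cytosolic ribosomal proteins were lower (median -0.07, 1 fall, adjusted p = 1.1e-04; adjusted p = 0.846 with an estimated correlation). Without Il33-/- pro-B replicate 1 this list had adjusted p = 0.983. Histones had a median of 2.74 with that library and of -0.38 without it. Their call followed that library (adjusted p = 1.3e-06 higher and 6.5e-04 lower; adjusted p = 0.797 and 0.587 with an estimated correlation).

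The other lists did not pass in pro-B cells. The adjusted p was 0.16 for p53 target genes (1 fall, Ddit4), 0.902 for CDK inhibitors and the RB family, 0.426 for the BCL2 family, 0.374 for NF-kB target genes and 0.144 for MYC targets and ribosome biogenesis. It was 0.343 for oxidative phosphorylation, 0.374 for mitochondrially encoded genes and 0.673 for chromatin partners and histone-related regulators. For markers of other cells it was 0.937 for granulocytes, 0.806 for monocytes and macrophages (1 rise and 1 fall, Ctss, lost without wild-type pro-B replicate 3), 0.503 for erythroid cells, 0.842 for megakaryocytes and 0.767 for T and NK cells. It was 0.668 for plasmacytoid dendritic cells, 0.374 for stem and multipotent progenitors, 0.902 for mast cells and basophils, 0.729 for stroma and 0.878 for sex-linked genes. Without Il33-/- pro-B replicate 1 oxidative phosphorylation turned from lower (median -0.03) to higher (0.04) and passed, with adjusted p = 0.047 (0.903 with an estimated correlation). Mitochondrially encoded genes (0.0498; 0.609 with an estimated correlation), NF-kB target genes (0.0391; 0.463) and V(D)J recombination (0.0326; 0.435) passed without it too, and cholesterol biosynthesis no longer did (0.0921).

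The pro-B test was an edgeR quasi-likelihood test across all 16 libraries. The lists were tested with camera at its preset correlation, where 15 of 37 passed and 3 held with an estimated correlation. The count of 207 fell to 113, 126 and 134 without wild-type pro-B replicate 3, wild-type pro-B replicate 1 and Il33-/- pro-B replicate 2. It was 225 without Il33-/- pro-B replicate 1, with 168 genes shared. Without scaling factors, which moved the median log2 fold change of all genes from -0.0076 to -0.13, the calls for Jchain, Igha, Ighg3, Iglc1, Cd38, Cd36, Ccnd3, Enpep, Oasl1, Polm, Srebf2, Hsp90b1 and Pdia4 were lost. Groups did not overlap at 1051 genes (6.83%), where chance gives 2.86%.

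The second comparison asks the same of large pre-B cells. Of the 4860 genes that fell with stage in wild type, 260, with Il33 itself among them, were lower still in Il33-/- large pre-B cells. Dntt, the terminal transferase that adds bases at V(D)J joints, went from 24.7 ± 12.4 to 2.95 ± 0.747 CPM. The inhibitory receptor gene Pdcd1 went from 5.27 ± 1.59 to 1.49 ± 0.426 CPM and the transcription factor gene Erg from 5.33 ± 2.08 to 1.58 ± 0.480 CPM. The surrogate light chain genes Igll1 and Vpreb1 went from 224 ± 60.0 to 113 ± 17.0 CPM and from 110 ± 29.5 to 61.5 ± 8.20 CPM. Hormad1 (0.931 ± 0.292 to 161 ± 5.03 CPM), Cux2 (0.406 ± 0.174 to 15.5 ± 1.79 CPM) and Zhx2 (8.68 ± 1.14 to 34.9 ± 1.22 CPM) rose as they did in pro-B cells. In total 481 genes passed, 162 higher and 319 lower in Il33-/- cells. Of the 319 lower genes 260 also fell and 29 rose with stage in wild type, and of the 162 higher genes 41 fell and 75 rose, where 31.6% and 28.9% of all tested genes did. Of the 481, 441 were protein-coding, 3 were segments and 126 changed more than 2-fold.

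Dntt (ENSMUSG00000025014, chromosome 19, 41029275 to 41059525) fell by 3.06 on the log2 scale (SE 0.36, adjusted p = 4.6e-04), Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553) by 1.81 (SE 0.20, adjusted p = 1.3e-05) and Erg (ENSMUSG00000040732, chromosome 16, 95359169 to 95586593) by 1.76 (SE 0.30, adjusted p = 0.0070). Alkbh7 fell by 1.72, Ccl25 by 1.46, the calcium pump gene Atp2b4 by 1.55 and Car12 by 1.54. Fzd9 (-1.70) lost its call without Il33-/- large pre-B replicate 1 or 3, and Ankrd13b (-1.58) without Il33-/- large pre-B replicate 1, 2 or 3. The largest rises were Hormad1 (7.43, SE 0.14, adjusted p = 4.0e-18), Cux2 (5.23, SE 0.18, adjusted p = 8.3e-16), Pak1 (2.42, SE 0.21, adjusted p = 1.1e-07) and Zhx2 (2.01, SE 0.16, adjusted p = 4.1e-07). They were joined by Erdr1 (2.21), Adarb2 (1.54), Mid1 (1.47) and Fsd1l (1.28), with Erdr1 and Mid1 uncertain as above. The chemokine receptor gene Ccr2 (1.41) lost its call without wild-type large pre-B replicate 1 or 3 or Il33-/- large pre-B replicate 1. Gpr179 (1.17) kept it without wild-type large pre-B replicate 3 alone.

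The surrogate light chain pairs with a new heavy chain in the pre-B cell receptor. Igll1 (ENSMUSG00000075370, chromosome 16, 16860671 to 16863985) fell by 0.99 (SE 0.16, adjusted p = 0.0041) and Vpreb1 (ENSMUSG00000059305, chromosome 16, 16868403 to 16870843) by 0.84 (SE 0.16, adjusted p = 0.013). Both missed the threshold in a fit of the large pre-B libraries alone. Of 26 genes of the pre-B cell receptor and its signalling 0 rose and 4 fell, or 2 and 5 adjusted over the list alone (list adjusted p = 0.303). This list had a median of 0.01 and a mean of -0.12, which differ in sign, as no list past the threshold did. The other falls were Ptpn6 (-0.30, adjusted p = 0.015, lost without wild-type large pre-B replicate 1 or Il33-/- large pre-B replicate 1 or 3) and Card11 (-0.46, adjusted p = 0.048). The call for Card11 was, of the large pre-B libraries kept only without Il33-/- replicate 4, and was lost also without Il33-/- pro-B replicate 1. Of the V(D)J recombination list Xrcc6 rose by 0.28 (adjusted p = 0.012) and Dntt fell, or 1 and 2 adjusted over the list alone (list adjusted p = 0.70). Of 29 early B cell identity genes Enpep rose by 0.33 (adjusted p = 0.043), a call lost without wild-type large pre-B replicate 2 or 4 or Il33-/- large pre-B replicate 1 or 3. Of these genes Erg fell, so that 1 rose and 1 fell, or 2 and 1 adjusted over the list alone (list adjusted p = 0.787).

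In the BCL2 family and IL-7 receptor signalling lists few members passed, and neither list did. Of 18 BCL2 family genes 0 rose and 3 fell, or 1 and 3 adjusted over the list alone (list adjusted p = 0.581). Bcl2 fell by 0.67 (SE 0.15, adjusted p = 0.012), a call lost without wild-type large pre-B replicate 1. Bid fell by 0.54 (adjusted p = 0.014), lost without that library or Il33-/- large pre-B replicate 1 or 3. Bok fell by 1.65 (adjusted p = 0.038), and kept its call only without wild-type large pre-B replicate 3 or 4 or Il33-/- large pre-B replicate 2. Of 24 genes of IL-7 receptor signalling 2 rose and 1 fell, or 3 and 4 adjusted over the list alone (list adjusted p = 0.408). Ccnd3 rose from 1123 ± 68.7 to 1408 ± 55.2 CPM (0.33, adjusted p = 0.0016), whereas Myc, at 22.3 ± 14.4 and 7.42 ± 3 CPM, did not pass (-1.58, SE 0.40, adjusted p = 0.056). Pdk1 fell from 8.44 ± 1.96 to 4.42 ± 0.719 CPM (-0.93, SE 0.14, adjusted p = 8.8e-04). It was the 1 fall of the glycolysis and hypoxia list (adjusted p = 0.0015; adjusted p = 0.815 with an estimated correlation). Of 49 MYC targets and ribosome biogenesis genes 1 was higher (median -0.19), 1 fell, Phb, and 0 rose (adjusted p = 8.6e-10; adjusted p = 0.815 with an estimated correlation). All 84 cytosolic ribosomal protein genes were lower (median -0.14, 1 fall, Rpl3l; adjusted p = 5.2e-10; adjusted p = 0.889 with an estimated correlation). Of them 20 fell without Il33-/- pro-B replicate 1. The calls for Phb and Rpl3l were each lost without any 1 of wild-type large pre-B replicates 1 to 3 and Il33-/- large pre-B replicates 1 to 3.

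Interferon-stimulated genes were higher in Il33-/- large pre-B cells. Of 38, 32 were higher (median 0.17). Of them 8 rose and 1 fell, or 12 and 1 adjusted over the list alone (adjusted p = 2.9e-09; adjusted p = 0.388 with an estimated correlation). Oas1a went from 1.74 ± 0.177 to 3.89 ± 0.785 CPM (1.16, SE 0.16, adjusted p = 1.7e-04), Oasl1 rose by 0.96 (adjusted p = 6.3e-04), Ifi27l2a by 0.97 (adjusted p = 8.3e-04) and Irf9 by 0.45 (adjusted p = 6.5e-04). The late pre-B, immature and mature B cell list was higher, with 3 rises and 1 fall, or 4 and 2 adjusted over the list alone (adjusted p = 0.039; adjusted p = 0.815 with an estimated correlation). Cd38 went from 87.7 ± 10.6 to 140 ± 9.41 CPM (0.67, adjusted p = 9.4e-04) and Lmo2 fell by 0.78 (adjusted p = 0.0019). The call for Iglc1 (1.31, adjusted p = 0.024) was lost without wild-type large pre-B replicate 1 or 2 or Il33-/- large pre-B replicate 1 or 2. Ltb (0.71, adjusted p = 0.034) lost its call without wild-type large pre-B replicate 2, 3 or 4 or Il33-/- large pre-B replicate 1 or 4. Of 14 plasma cell markers 8 were higher, and 3 rose and 1 fell adjusted over the list alone (list adjusted p = 0.424). Igha among them stood at 22.8 ± 12.6 CPM in wild-type and 55.4 ± 5.53 CPM in Il33-/- large pre-B cells, without passing over all genes. Heavy chain V segments had 1 rise, Ighv9-3, or 0 adjusted over the list alone (list adjusted p = 0.034; adjusted p = 0.638 with an estimated correlation). Light chain V segments had 1, Iglv1, and 1 adjusted over the list alone (list adjusted p = 0.0534). Without Il33-/- pro-B replicate 1 the light chain list passed (adjusted p = 0.0447; adjusted p = 0.849 with an estimated correlation).

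Il33 and Il18 were the 2 falls of the IL-1 and IL-33 family list, or 3 adjusted over the list alone (adjusted p = 0.0104; adjusted p = 0.202 with an estimated correlation). Il18 fell by 1.24 (adjusted p = 0.0067). The DNA replication list (adjusted p = 0.025; 0.969 with an estimated correlation) and the E2F list (0.019; 0.969; 1 fall, Tk1) were slightly higher. So was the list of CDK inhibitors and the RB family, which are inhibitors of the cell cycle (0.045; 0.867; 1 rise, Rb1). Oxidative phosphorylation was lower (adjusted p = 0.012; adjusted p = 0.969 with an estimated correlation), as was cholesterol biosynthesis with 1 fall, Srebf2, or 4 adjusted over the list alone (adjusted p = 0.0025; adjusted p = 0.815 with an estimated correlation). The adjusted p was 0.81 for G2/M and mitosis, p53 target genes, NF-kB target genes, megakaryocyte and stroma markers. It was 0.289 for the unfolded protein response (1 fall, Asns) and 0.224 for immediate early genes. It was 0.951 for chromatin partners (2 falls, Dnmt3b and Hmga2), mitochondrially encoded genes, plasmacytoid dendritic cells and mast cells, and 0.822 for monocytes, T and NK cells and sex-linked genes. It was 0.911 for granulocytes, 0.914 for erythroid cells, 0.97 for stem and multipotent progenitors and 0.321 for histones, where 3 fell without Il33-/- pro-B replicate 1 (adjusted p = 2.8e-08; adjusted p = 0.736 with an estimated correlation).

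The large pre-B test was the same edgeR test. Of 37 lists 12 passed camera and 0 held with an estimated correlation, where fry gave 2. The count of 481 genes was 227, 236, 250 and 284 without Il33-/- large pre-B replicate 3, wild-type large pre-B replicate 1 and Il33-/- large pre-B replicates 1 and 2. Of these 137, 142, 170 and 171 were lower, and 112, 114, 143 and 137 of those fell with stage in wild type. The whole count was 623, with 472 shared, without Il33-/- pro-B replicate 1, which enters the fit. The calls for Tk1, Rb1, Srebf2, Asns, Hmga2, Ighv9-3 and Iglv1 were each lost without wild-type large pre-B replicate 1 and without Il33-/- large pre-B replicate 1, and all but Iglv1 were also lost without other single large pre-B libraries. Without scaling factors the calls for Ccnd3, Irf9, Xrcc6, Enpep, Iglc1, Ptpn6, Card11, Bok, Phb, Rpl3l, Tk1, Rb1, Srebf2 and Ighv9-3 were lost. Groups did not overlap at 1726 genes (11.2%), where chance gives 2.86%.

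The difference of the genotype effects between the stages was then tested in itself. The cyclin-dependent kinase gene Cdk6 stood at 507 ± 17.9 and 515 ± 23.7 CPM in wild-type and Il33-/- pro-B cells and at 192 ± 27.5 and 126 ± 7.18 CPM in large pre-B cells. Pdcd1 stood at 21.8 ± 2.13 and 18.7 ± 1.5 CPM in pro-B cells, against 5.27 and 1.49 CPM in large pre-B cells. In the edgeR test 2 genes passed, Cdk6 (ENSMUSG00000040274, chromosome 5, 3341485 to 3531008) with a difference of -0.64 (SE 0.10, adjusted p = 0.033) and Pdcd1 with -1.58 (SE 0.25, adjusted p = 0.033). The next by p were Rgs10 (0.84, adjusted p = 0.058), Mmrn1 (-3.33, 0.058), Igkc (-0.78, 0.058), Dntt (-2.83, 0.078), Adgrg1 (0.39, 0.078), Fam129c (0.54, 0.087), Ighv1-21 (-1.71, 0.087) and Colq (-0.65, 0.087), which did not pass. So the falls of Dntt, Erg (adjusted p = 0.215), Igll1 (0.501) and Vpreb1 (0.825) in large pre-B cells were not shown to differ from the effects in pro-B cells. Neither did the interaction pass for Hormad1 (0.907), Cux2 (0.437), Zhx2 (0.498) or Il33 (0.815).

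The change of the immunoglobulin V segments was larger in pro-B cells. Heavy chain V segments differed between the stages (adjusted p = 9.3e-11; adjusted p = 0.0032 with an estimated correlation). This was the 1 of 8 list calls that held with an estimated correlation. Light chain V segments had adjusted p = 1.1e-04 (0.187 with an estimated correlation), plasma cell markers 0.00518 (0.0739), the unfolded protein response 9.1e-05 (0.368) and MYC targets 2.8e-06 (0.87). Interferon-stimulated genes had 0.0433 (0.87), ribosomal proteins 0.0174 (0.959) and histones 7.7e-13 (0.87; 0.28 at the preset correlation without Il33-/- pro-B replicate 1). Without that library interferon-stimulated genes also missed the threshold (0.0511). DNA replication, the E2F list, G2/M and mitosis, oxidative phosphorylation and NF-kB target genes passed without it, with adjusted p from 0.65 to 0.79 with an estimated correlation. Cdk6 alone lost its call without wild-type pro-B replicate 3 or Il33-/- pro-B replicate 3, and without scaling factors. The edgeR count of 2 genes was 0 without Il33-/- pro-B replicate 4, wild-type large pre-B replicate 2 or Il33-/- large pre-B replicate 2 or 4. It was 1 without wild-type pro-B replicate 1 or 4, where neither Cdk6 nor Pdcd1 passed, and 1, Cdk6, without Il33-/- large pre-B replicate 1. It was 12 without wild-type pro-B replicate 2, 10 without wild-type large pre-B replicate 4, 8 without Il33-/- pro-B replicate 1 and 4 without wild-type pro-B replicate 3, Il33-/- pro-B replicate 3 or Il33-/- large pre-B replicate 3.

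Both stages shared part of their genotype differences. Hormad1, Cux2, Zhx2, Pak1 and Adarb2 were higher and Il33, Tfe3, Gimap4, Alkbh7 and Ccl25 lower at both. Of the 207 and 481 calls 90 were common, against 6.48 by chance. Of these, 48 were higher at both stages (1.16 by chance), 42 were lower at both (2.01 by chance) and 0 went opposite ways. Across the 15377 genes, which are not independent replicates, the log2 fold changes of the stages had a Pearson correlation of 0.292 and a Spearman correlation of 0.344. In the test of the mean of both stages 1119 genes passed, 443 higher and 676 lower. Interferon-stimulated genes rose in 12 members and fell in 1, or 15 and 1 adjusted over the list alone (adjusted p = 4.7e-09; adjusted p = 0.163 with an estimated correlation). Of 37 lists 15 passed and 3 held with an estimated correlation, which were heavy chain V segments (adjusted p = 0.00284), light chain V segments (0.0476) and the IL-1 and IL-33 family (0.0476), the last holding Il33 itself. Without Il33-/- pro-B replicate 1 light chain V segments (adjusted p = 0.135 with an estimated correlation) and the IL-1 and IL-33 family (0.0517) did not hold. Without it histones turned from higher to lower for the mean (adjusted p = 0.55 with an estimated correlation), oxidative phosphorylation no longer passed (0.561), and G2/M and mitosis passed (8.4e-04; 0.755 with an estimated correlation).

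**Figure D4:**
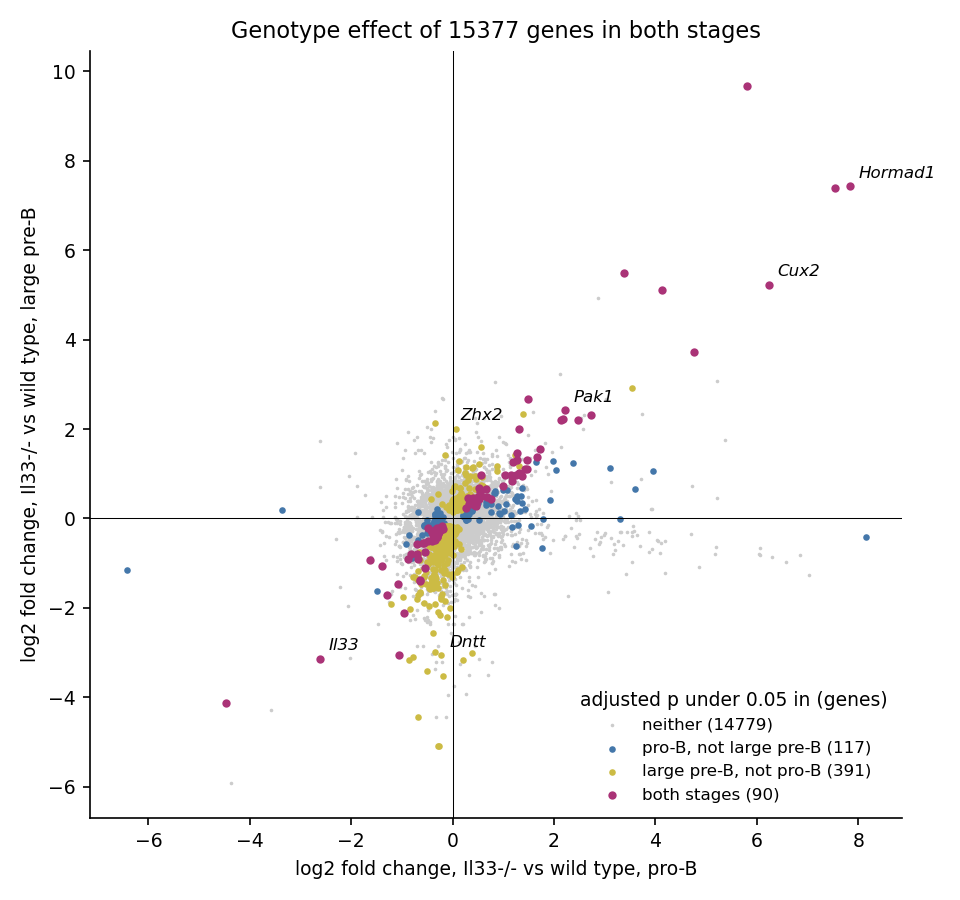
Log2 fold change Il33-/- over wild type in pro-B cells (horizontal axis) and in large pre-B cells (vertical axis) for 15377 genes (points), coloured by where they passed the threshold. Of these, 90 passed at both stages, 117 in pro-B and not in large pre-B cells and 391 in large pre-B and not in pro-B cells; in itself the difference between stages passed for 2 genes.

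A targeted gene can carry DNA of another strain beside it, so genes near Il33 were counted. Within 10 Mb of Il33 on chromosome 19, 0 of 87 tested genes passed in pro-B cells in edgeR (7 at an unadjusted p under 0.05), against 205 of 15213 elsewhere (Fisher exact p = 0.634, two-sided). In large pre-B cells 1 of 87 passed, Anxa1, chosen after its values were seen, against 477 elsewhere (Fisher exact p = 0.528), and 11 had an unadjusted p under 0.05. For the mean of both stages 5 of 87 passed against 1111 elsewhere (Fisher exact p = 0.835). Within 20 Mb it was 2 of 246 in pro-B, 10 of 246 in large pre-B (Fisher exact p = 0.355) and 19 of 246 for the mean (Fisher exact p = 0.804). Dntt, outside the 10 Mb window, was among the 10 and the 19.

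The third comparison follows wild-type cells from pro-B to large pre-B. The stem cell factor receptor gene Kit went from 25.9 ± 4.08 to 0.663 ± 0.327 CPM (log2 fold change -5.30, SE 0.23, adjusted p = 2.7e-13). Dntt went from 1203 ± 157 to 24.7 ± 12.4 CPM. Syk, the kinase of the pre-B cell receptor, rose from 576 ± 14.6 to 1648 ± 176 CPM (1.52, SE 0.07, adjusted p = 1.6e-14). The transcription factor gene Spib went from 287 ± 36.2 to 982 ± 93.0 CPM (1.78, SE 0.08, adjusted p = 2.2e-14) and Il2ra, which encodes CD25, from 16.3 ± 1.74 to 82.7 ± 8.66 CPM (2.34, SE 0.09). Division genes rose too, such as the mitotic kinase gene Nek2, from 138 ± 8.16 to 398 ± 34.0 CPM. In total 9306 genes passed, 4446 higher and 4860 lower in large pre-B cells, and 2856 of them changed more than 2-fold.

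The largest rises with stage in wild type were Shank2 (3.57, SE 0.34), Myzap (3.47, SE 0.21), Lrrc10b (3.36), Cldn10 (3.34), Prg3 (3.21), C1qc (3.20), the class II transactivator gene Ciita (3.18, SE 0.15), Nrxn1 (3.17), Atoh8 (3.10) and Cd2 (3.09). The largest falls were Speer2 (-7.95, of a multigene family and uncertain), Robo4 (-7.57, SE 0.43), Nebl (-7.40), Tnfrsf8 (-6.72, SE 0.50), Als2cl (-6.45), Ttpa (-6.38), Trpa1 (-6.38), Ccdc33 (-6.20), Rab6b (-6.13) and Dkk3 (-6.10). The groups did not overlap in any of these 20 genes, as at 8790 genes (57.2%) in all, where chance gives 2.86%.

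Cell division lists were higher in large pre-B cells. All 59 genes of the G2/M and mitosis list rose (median 1.12; adjusted p = 5.9e-55; adjusted p = 0.172 with an estimated correlation), with Nek2 at 1.53, Prc1 at 1.32, Espl1 at 1.24 and Psrc1 of the p53 list at 1.21. Of 49 DNA replication genes 43 rose and 1 fell (adjusted p = 2.3e-09; adjusted p = 0.382 with an estimated correlation). Of 40 E2F genes 35 rose and 2 fell, with E2f2 at 1.41 (adjusted p = 1.3e-13; adjusted p = 0.237 with an estimated correlation). Both counts were the same adjusted over the list alone. Of 15 CDK inhibitors and RB family genes 13 rose and 1 fell, or 14 and 1 adjusted over the list alone (adjusted p = 1.4e-08; adjusted p = 0.172 with an estimated correlation), with Cdkn2c at 1.53 and Cdkn2d at 1.76. Chromatin partners rose in 19 members and fell in 6 (adjusted p = 0.0275; adjusted p = 0.237 with an estimated correlation). Histones rose in 6 and fell in 0, or 4 and 0 adjusted over the list alone (adjusted p = 0.115), and 52 rose without Il33-/- pro-B replicate 1 (adjusted p = 1.8e-05; adjusted p = 0.413 with an estimated correlation).

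Pre-B cell receptor genes rose in 15 of 26 and fell in 7, or 16 and 7 adjusted over the list alone (adjusted p = 0.042; adjusted p = 0.237 with an estimated correlation), with Klf2 at 2.39, Syk, Irf4 at 1.21 and Lyn at 1.10. Late pre-B, immature and mature B cell genes rose in 17 and fell in 4 (adjusted p = 3.9e-06; adjusted p = 0.234 with an estimated correlation), with Fcrla at 2.29, Il2ra, H2-Ab1 at 2.10 and Cd72 at 1.46. Heavy chain V segments rose in 60 and fell in 10 (adjusted p = 0.0224; adjusted p = 0.237 with an estimated correlation). Early B cell identity genes rose in 16 and fell in 8, or 17 and 8 adjusted over the list alone (adjusted p = 0.0508), with Spib, Bach2 at 1.5, Ikzf1 at 1.06 and Pou2af1 at 0.99. Without Il33-/- pro-B replicate 1 this list passed (adjusted p = 0.0153; adjusted p = 0.549 with an estimated correlation).

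MYC targets and ribosome biogenesis genes fell in 47 of 49 and rose in 1, Tfrc (median -0.90; adjusted p = 1.2e-11; adjusted p = 0.459 with an estimated correlation). Glycolysis and hypoxia genes fell in 22 and rose in 2, or 22 and 3 adjusted over the list alone (adjusted p = 5.5e-06; adjusted p = 0.237 with an estimated correlation), with Ndrg1 at -3.94 and Pdk1 at -2.59. Interferon-stimulated genes fell in 31 and rose in 4 (median -1.10; adjusted p = 3.1e-05; adjusted p = 0.237 with an estimated correlation), with Oas3 at -3.69 and Gbp2 at -2.40. Stem and multipotent progenitor markers fell in 6 and rose in 1 (adjusted p = 0.0036; adjusted p = 0.172 with an estimated correlation), with Kit and Flt3 (-4.17) among them.

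The lists that did not pass with stage in wild type had adjusted p = 0.333 for p53 target genes (15 rose, 12 fell), 0.522 for the BCL2 family (6, 8), 0.324 for V(D)J recombination (8, 5), 0.43 for IL-7 receptor signalling (7, 13) and 0.759 for NF-kB target genes (7, 8). It was 0.578 for oxidative phosphorylation (14, 7), 0.672 for cholesterol biosynthesis (7, 10), 0.642 for the unfolded protein response (9, 10), 0.908 for immediate early genes (8, 9) and 0.115 for the IL-1 and IL-33 family (3, 10). It was 0.192 for light chain V segments (5, 42), 0.235 for mitochondrially encoded genes (7, 0) and 0.134 for ribosomal proteins (0, 40; adjusted p = 0.0312 without Il33-/- pro-B replicate 1 and 0.876 with an estimated correlation there). Markers of other cells had adjusted p = 0.165 for granulocytes (0, 8), 0.759 for monocytes (8, 5), 0.874 for erythroid cells (1, 2), 0.759 for megakaryocytes (1, 0) and 0.103 for T and NK cells (0, 5). It was 0.112 for plasma cells (2, 9), 0.513 for plasmacytoid dendritic cells (3, 6), 0.522 for mast cells (2, 1), 0.978 for stroma (5, 4) and 0.874 for sex-linked genes (0, 0).

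The last comparison follows Il33-/- cells over the same step. Il33-/- cells lost Kit (31.7 to 0.415 CPM) and Dntt (1024 ± 186 to 2.95 ± 0.747 CPM) and gained Syk (594 to 1674 CPM), Spib (292 to 1098 CPM) and Nek2 (145 to 391 CPM). In total 9442 genes passed, 4509 higher and 4933 lower. All 59 G2/M genes rose (adjusted p = 1.3e-49; adjusted p = 0.141 with an estimated correlation). Of 49 MYC targets 47 fell and 1 rose (adjusted p = 3.8e-15; adjusted p = 0.356 with an estimated correlation), and 28 interferon-stimulated genes fell and 4 rose (adjusted p = 4.1e-04; adjusted p = 0.356 with an estimated correlation). Light chain V segments fell in 54 and rose in 4 (adjusted p = 0.0264; adjusted p = 0.34 with an estimated correlation). Plasma cell markers fell in 12 and rose in 2 (adjusted p = 0.0264; adjusted p = 0.141 with an estimated correlation). The other lists past the threshold were DNA replication, the E2F list, CDK inhibitors and the RB family, early B cell identity, late B cell genes, glycolysis and hypoxia, chromatin partners, stem and multipotent progenitors and ribosomal proteins, with adjusted p from 0.141 to 0.872 with an estimated correlation. Heavy chain V segments, which passed in wild type, did not pass in Il33-/- cells (31 rose, 15 fell, adjusted p = 0.472), and this difference passed (adjusted p = 0.0032 with an estimated correlation). The pre-B cell receptor list did not pass either (adjusted p = 0.0778), a difference from wild type that did not pass (adjusted p = 0.313), and it passed without Il33-/- pro-B replicate 1 (adjusted p = 0.0243; adjusted p = 0.302 with an estimated correlation). Histones had adjusted p = 0.965, and 47 rose without that library (adjusted p = 3.1e-04; adjusted p = 0.469 with an estimated correlation). Both stage tests used edgeR on the same 16 libraries. Camera passed 12 lists in wild type and 14 in Il33-/- cells, and 0 of either held with an estimated correlation, where fry gave 26 and 29.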

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

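The tests of the large pre-B, immunoglobulin and segment explanations were chosen after the results they measure were seen, whereas the test around Il33 and the counts of other splits were planned. Chosen after as well were the threshold for genes restricted to pro-B cells (a log2 fall with stage of at least 6 in Il33-/- cells, or of at least 5 where chosen in wild type), the subsets of plasma and late B cell genes, the count of shared genes on other chromosomes, and the 16 genes looked at for outlying libraries.

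Il33-/- pro-B replicate 1 lay apart from the other 3 libraries of its group in 7 measures. It held 7.96 M counts (others 25.1 to 27.0), 18500 genes with a read (20956 to 21139), a TMM factor of 0.694 (1.07 to 1.09), 38.5% ribosomal RNA (0.278 to 0.321), 0.164% histone (0.0126 to 0.0179), 2.92% ribosomal protein (5.56 to 5.91) and 39.4% of its counts in the 10 highest genes (3.63 to 3.71). In other groups, Il33-/- large pre-B replicate 2 held 30 M counts (others 27.4 to 27.7) and Il33-/- large pre-B replicate 4 had 4.68% ribosomal protein (4.15 to 4.17). Histones took 0.0290% in wild-type large pre-B replicate 1 (0.0362 to 0.0377). Dntt stood at 1301 CPM in Il33-/- pro-B replicate 3 (917 to 958), and Erg in the same library at 240 CPM (192 to 199.6). Cdk6 stood at 136 CPM in Il33-/- large pre-B replicate 1 (121 to 122) and Vpreb1 at 697 CPM in wild-type pro-B replicate 2 (848 to 878). These are 14 outlying values, from 7 libraries, in 104 groups of 4 looked at, where chance gives about 1 in 20, or 5.20.

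The genotype effect differed between the stages for Pdcd1 (-1.58) and Cdk6 (-0.638). For lists the adjusted p of that difference was 0.0433 for interferon-stimulated genes, 2.77e-06 for MYC targets, 9.09e-05 for the unfolded protein response, 0.00518 for plasma cell markers, 7.73e-13 for histones, 9.25e-11 for heavy chain V segments, 1.06e-04 for light chain V segments and 0.0174 for ribosomal proteins. With an estimated correlation only heavy chain V segments held (0.0032), and the others had adjusted p from 0.0739 to 0.959. Histones (0.28) and interferon-stimulated genes (0.0511) were lost at the preset correlation without Il33-/- pro-B replicate 1.

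Genes of the pro-B stage, such as Pdcd1, Igll1, Dntt and Erg, were lower in Il33-/- large pre-B cells, and of 319 falls there 260 also fell with stage in wild type. Pro-B cells in the wild-type large pre-B sort could bring falls, but the 15 genes most restricted to pro-B cells bound their share at 3.43%. Falls beyond what it allows numbered 85, with Pdcd1, Igll1 and Cdk6 (adjusted over all 4860 genes that fell with stage). Of 75 rises 27 went beyond a dilution of 0.05 (adjusted over all 4446 that rose). The 85 held Il33 itself, the targeted gene, and genes also called lower in Il33-/- pro-B cells, such as Tfe3, Alkbh7, Park7 and Ccl25. They do not all stand for falls called in large pre-B cells alone. Such pro-B cells are not the whole source of these 85 falls and 27 rises. For the other 175 falls, with Dntt, Erg, Atp2b4 and Vpreb1, and 48 rises they cannot be told apart from a change in the cells, since 18 restricted genes chosen in wild type alone also kept more of their pro-B level in wild-type (1.22 to 3.4%) than in Il33-/- libraries (0.577 to 0.751%). The falls numbered 142 without wild-type large pre-B replicate 1 and 137, 170 and 171 without Il33-/- large pre-B replicates 3, 1 and 2, but 114 of the 142 fell with stage, so no 1 wild-type library is the source of the whole pattern. Cells between the stages, in other numbers within the large pre-B gate, or faster loss of the pro-B programme without Il33, stay open and untested.

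Immunoglobulin and plasma cell transcripts were higher in Il33-/- pro-B cells. The values go with a few plasma cells in that sort, since 9 of 10 plasma cell markers that are not immunoglobulin genes were higher (camera p = 0.00262 with an estimated correlation), although only Jchain of them was called, their median was 0.225 (SE 0.208) against 1.08 for light chain constant genes, and CD19 enrichment would remove plasma cells that lack CD19. Igha stood at 802 CPM and Igkc at 600 CPM, against 258 and 319 CPM in wild type. The more abundant Ighm stood at 3216 ± 118 CPM, against 3044 ± 196 CPM in wild type. Immature and mature B cells cannot be told apart from the other sources, since 27 of their genes that are not immunoglobulin had a median of 0.112 (SE 0.0859) but went both ways, with 18 higher, 3 called and Ms4a1 lower (9.48 and 8.59 CPM, not called), and their own level in pro-B cells would hide a small share (camera p = 0.00209; 0.118 with an estimated correlation). Another heavy chain haplotype that acts alike at both stages is argued against as the only source, since the V segments differed between the stages (camera adjusted p = 0.0032 with an estimated correlation). One that acts more at 1 stage, or beside other sources, stays open, as plasma cells alone could bring such a difference. A change of germline or rearranged transcription in the pro-B cells without Il33 may be present too and was not tested.

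Differences shared by both stages, such as Hormad1, Cux2 and Zhx2, may come from DNA of another strain, but such DNA around Il33, acting on genes beside it, is argued against as the source of most of them, since 88 of 89 shared genes lie on other chromosomes. Whether it adds a few cannot be told apart, as 5 of 87 genes within 10 Mb were called for the mean (Fisher exact p = 0.835, odds ratio 0.774 with an upper 95% bound of 1.89; 1.06 within 20 Mb). Elsewhere it stays open, since 22 of 86 genes called in both stages had another that did not overlap them within 1 Mb, where random sets had a median of 12 and 14 of 1000 sets had as many. Such clusters held Hormad1 with Ctss, Cux2 with Rasal1 and Aldh2, and Alkbh7 with Ptprs. The labels do not give the lines or their breeding, and effects of Il33 and of such segments stay untested against each other.

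Other splits of the same libraries gave the following. No other split reached the real gene count in pro-B (207, highest other 31, 1 of 35 splits as large), large pre-B (481, 4, 1 of 35), stage in wild type (9306, 10, 1 of 35), stage in Il33-/- (9442, 2, 1 of 35) or the mean (1119, 65, 1 of 100). Nor did any reach the correlation of both effects (0.292, 0.135, 1 of 100). For these a chance split of the libraries is argued against, although 1 of 35 is the smallest share that 35 splits can give. Chance differences between animals are not excluded, since the labels do not say whether the libraries came from separate animals. For the difference between stages (2, 86, 4 of 100) the splits cannot settle whether chance gave the count. The split calling 86 genes, and the 2 others as large, kept the large pre-B genotypes whole and so still held that genotype effect. The 2 genes became 0 without any 1 of 4 libraries. For lists at the preset correlation the mean (15, 18, 4 of 100) had a share of 0.04. Another split passed more lists than it, and the other splits had a median of 10, so that share does not by itself exclude chance. Chance was not excluded for pro-B (15, 16, 6 of 35), large pre-B (12, 16, 9 of 35), the difference (8, 16, 69 of 100), stage in wild type (12, 17, 20 of 35) or stage in Il33-/- (14, 16, 10 of 35).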

How the results depend on the processing

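The tests without ribosomal RNA genes, without Il33-/- pro-B replicate 1 where a comparison does not use it, without single libraries for the correlation and the window, and with upper quartile factors or the CPM filter for lists were chosen after the data were seen. Il33 stayed lower and past the threshold under every alternative run, between -2.77 and -2.47 in pro-B and between -3.27 and -2.99 in large pre-B cells. Of 207 genes in pro-B cells, DESeq2 called 438 (201 shared), limma-voom 339, quality weights 756, protein-coding genes alone 119, an adjusted p under 0.01 91 and at least 1.5-fold 98, with 113 to 266 when 1 library was left out (113 without wild-type replicate 3, 126 without wild-type replicate 1, 134 without Il33-/- replicate 2). Of 481 in large pre-B cells, no scaling factors gave 249, DESeq2 871 (472 shared), quality weights 798, the stricter p 169 and 1.5-fold 230, with 227 to 623 when 1 library was left out (227 without Il33-/- replicate 3, 236 without wild-type replicate 1, 250 and 284 without Il33-/- replicates 1 and 2). The 2 genes of the difference between stages became 4 with DESeq2 size factors, 21 with no filter, 4 with at least 1 CPM in 4 libraries, 60 with DESeq2, 1 with limma-voom, 37 with quality weights, 4 among protein-coding genes, 0 under the stricter p and 0 to 12 without 1 library. At least 1.5-fold left 4742 of 9306 genes with stage in wild type and 4939 of 9442 in Il33-/-. The mean of both stages (1119) gave 592 without scaling factors, 1717 with quality weights, 410 under the stricter p and 294 at 1.5-fold. Fewer genes pass a stricter p or fold by construction, and for the other changes the cause was not tested. Without scaling factors the share of calls that were higher went from 53.1 to 39.6% in pro-B, from 47.8 to 27.6% with stage in wild type and from 39.6 to 24.0% for the mean, and the median of all genes moved to -0.13, -0.18 and 0.12 in pro-B, stage in wild type and the difference.

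Lists past the threshold went from 15, 12, 8, 12, 14 and 15 (pro-B, large pre-B, difference, stage in wild type, stage in Il33-/- and mean) to 3, 0, 1, 0, 0 and 3 with an estimated correlation and to 4, 2, 2, 26, 29 and 8 by fry, and the difference to 5 without scaling factors. Without 1 library there were 12 to 17, 7 (without wild-type large pre-B replicate 3) to 14, 5 (without Il33-/- pro-B replicate 4) to 13 (without wild-type pro-B replicate 2), 10 to 15, 12 to 16 and 13 to 16. The correlation of both effects ran from 0.237 without wild-type large pre-B replicate 1 to 0.369 without Il33-/- pro-B replicate 1, and genes near Il33 numbered 0 to 1 in pro-B and 1 in large pre-B cells without any 1 library. Of named genes, 24 of 46 called in pro-B, 24 of 54 in large pre-B, 0 of 2 in the difference and 151 of 160 with stage kept their call in every alternative run, and 0 reversed. The histone lists of pro-B and of the mean changed direction without Il33-/- pro-B replicate 1. Fits of the compared groups alone were not run for the difference and the mean, which use all groups. Depth limits Il33-/- pro-B replicate 1, with 4.90 M counts outside ribosomal RNA.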

Other observations

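The genes named in this part were chosen after their values were seen, as were the tests of segments of DNA and of the relation to stage; the correlation of both genotype effects was planned.

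At the Zhx2 locus on chromosome 15, 2 antisense genes went the other way from Zhx2. 9330154K18Rik (57736563 to 57738666) fell from 1.58 to 0.0552 CPM in pro-B cells (log2 fold change -4.47, SE 0.70, adjusted p = 0.0012) and from 2.14 to 0.118 CPM in large pre-B cells (-4.13, SE 0.59, adjusted p = 3.4e-04), while Zhx2 rose by 1.30 and 2.01. Gm16006 (57708114 to 57708927) fell in pro-B cells (adjusted p = 0.0030) and did not pass in large pre-B cells (adjusted p = 0.316). At Cux2, the antisense gene Gm15637 (122048382 to 122055654) rose with it, by 5.80 in pro-B cells. The pseudogene Gm15529 on chromosome 6 went from 0.00919 to 2.49 CPM in pro-B and from 0.00981 to 2.49 CPM in large pre-B cells. In BALB/c mice Zhx2 is known for an allele of low expression in a substrain, which is background and was not tested.

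The genotype effects ran partly along the stage difference. Of the 97 genes lower in Il33-/- pro-B cells 72 fell and 10 rose with stage in wild type, and of the 110 higher 20 fell and 55 rose. With stage in Il33-/- cells 64 of the 97 fell and 13 rose, and of the 110 higher 33 fell and 38 rose, where 32.1% and 29.3% of tested genes did. In large pre-B cells, of the 162 higher 41 fell and 75 rose in wild type, and 36 and 87 in Il33-/-. In 20 simulations with no genotype effect as many genes of lowest p held, among the lower, 17 to 33 falls for pro-B and 91 to 133 for large pre-B. Among the higher they held 34 to 52 and 48 to 72 rises with stage in wild type. The observed 55 and 75 lay slightly above the highest of these. Across the 15377 genes, which are not independent replicates, the genotype effect correlated with the stage effect at 0.293 in pro-B and 0.278 in large pre-B cells. Both use the same wild-type libraries, so the wild-type libraries were divided between both effects in 6 ways, which gave values from 0.152 to 0.323 and from 0.154 to 0.415. Data simulated with no genotype effect gave 0.0198 and -0.0393. The covariance was 0.0429 and 0.0364, against 0.00143 and -0.00251 in the simulated data. The simulations drew each gene on its own, so simulated libraries could not shift together along the stage difference, as real ones can. The wild-type large pre-B libraries ran from -41.5 to -63.6 on the first principal component, which parts the stages. So the simulated values and counts do not tell an effect of genotype apart from such a shift between libraries.

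The third principal component held 4.45% of the variance. On it the large pre-B libraries lay from 13.59 to 24.15 in wild type and from -18.59 to -12.61 in Il33-/- cells. Of the pro-B libraries, 3 Il33-/- ones lay at -18.5, -22.2 and -16.7 and the wild-type ones between 4.23 and 16.2. Against this, Il33-/- pro-B replicate 1 lay at 9.84 with the wild type. In that library Hormad1 stood at 140.9 CPM (146.8 to 184.2 in the other 7 Il33-/- libraries) and Cux2 at 26.6 CPM (13.1 to 24.6).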
